A study of Arabidopsis thaliana with 4 samples.

How the data were processed

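Messenger RNA of whole seedlings was selected with oligo(dT) beads and sequenced, per the labels' protocols. The protocols list a cold period of 4 days, which preceded the 4.5 days of growth, so it was no treatment of grown seedlings. WT and phyB mutant seedlings then grew in white light for 12 h and red light for 4 days, on medium with 1% sucrose. Samples were grouped by the genotype in the labels, with 2 samples per genotype. The values consist of 1 read column and 1 RPKM column per genotype, per the file headers. Whether a column sums both samples of a genotype or holds a single library is not given in the sources used here, so each was used as the authors' value with no SD and no n.

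The deposited read columns were treated as estimated counts, since the authors wrote 0.5 where a gene model had 0 reads, while all other entries were whole numbers. There were 4164 such entries in WT and 4100 in phyB, with 3504 models at 0 reads in both, and they were set back to 0 here. The deposited RPKM values equal the reads divided by a coding length per gene model and by the column total without the 0.5 entries, as recomputed from the values. The lengths implied by both columns were whole numbers within 0.001 nt, and 99.99% were multiples of 3, so they are called coding lengths. The genome build is TAIR10 per the submitters' processing notes. The aligner, the counter, their versions, the treatment of reads with several matches and the use of strand are not given in the sources used here.

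Gene names, products, positions and overlaps came from the RefSeq annotation of TAIR10.1, in which 26719 of the 27206 nuclear gene models had a gene. The implied length of 95.0% of nuclear models equalled a reference coding length. Of the 62 genes named by the rule below, 20 overlap a gene on the opposite strand and 3 a gene on the same strand, and 4 have a coding sequence elsewhere with at least 90% identity over 80% of the length in a BLAST 2.17.0 search. Those values can include reads of the other gene.

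The difference between genotypes was the log2 ratio of deposited RPKM, phyB over WT, with no pseudocount. A column with 0 reads was set to a floor of 3 reads for this ratio, which makes it a bound. The design, the 20 gene lists and the rule for named genes were fixed before the data were examined. For 1 value per genotype the design foresaw no test, only both values and their fold, and the log2(RPKM + 1) scale it named for a replicated test served as an alternative. Intervals are exact conditional 95% intervals (Clopper-Pearson) from both read counts and totals. Reads copied by PCR without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Genes with a mean of at least 1 RPKM were described. The filter set at the outset was for values in single libraries, and the mean of both columns took its place.

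For the 20 gene lists, with 395 entries, the median log2 ratio of the measured members was placed among those of 10000 random lists of nuclear genes of the same size, matched on 20 classes of mean expression. Medians outside the 2.5 to 97.5 percentiles are described as standing apart. The 4 further lists with 57 entries were chosen after values were seen and appear only in the closing section. The named genes are PHYB with the other phytochrome and PIF genes, the 6 largest higher and 6 largest lower ratios of at least 2-fold with a mean of at least 5 RPKM outside the organelles and transposable elements, and up to 4 members per list with a ratio of at least 2-fold and 5 RPKM in either genotype, or else the member of highest mean. That last step was stated for replicated values and was carried over to single values. Other genes named were chosen after their values were seen.

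On simulated counts drawn for the 19297 described genes of the phyB against WT comparison, with 200 genes changed, 2.0% of genes simulated at 1.5-fold, 96.0% at 2.5-fold and 100% at 4-fold and 8-fold were placed at 2-fold or more in the right direction. Of the unchanged genes 37 reached 2-fold from counting noise alone, and 95.7% of the 95% intervals held the simulated value. For the list step, 20 lists of 20 genes each were drawn at random with their measured ratios. With 0.5 added to the ratios of a list, all 20 lay above the 97.5 percentile, and 0 of the 20 unshifted lists stood apart. Genes drawn at random are not chosen for shared regulation or reads. The check therefore does not show how often a list of related genes would stand apart. The simulation held no variation between seedlings.

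The alternatives set at the outset and run were quantile normalization and median scaling of RPKM, RLE and upper-quartile factors from edgeR 4.0.16 on the read columns, no filter, a mean of at least 5 RPKM, pseudocounts of 1 and 0.1, and an absolute log2 ratio of 1.5. Added after the data were seen were TMM factors, removal of a lowess trend of the log2 ratio on log2 coding length (span 0.3, statsmodels 0.14.6), totals without organelle genes, a counting interval wholly beyond 2-fold, and random lists matched also on coding length. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3.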

Results

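Transcripts of Arabidopsis thaliana seedlings of the Col-0 accession were sequenced from the wild type (WT) and from a mutant in phytochrome B (phyB), the main red-light receptor of light-grown seedlings. All seedlings had grown for 4.5 days, which per the growth protocol were 12 h of white light followed by 4 days of red light, at 60 μmol per m2 per s. The labels list 4 samples, 2 per genotype, but the values used here consist of 1 column per genotype, so no value had a replicate check. The WT column held 33521717 reads and the phyB column 33201394 reads over the same 27416 gene models. The 10 most abundant genes took 5.37% of the reads in WT and 5.42% in phyB. Chloroplast genes took 1.87% and 2.18%, and mitochondrial genes 0.0475% and 0.103%. The titles of the WT samples, unlike those of the mutant, carry a word for a repeated analysis whose meaning is not given, so a batch and the genotype cannot be told apart.

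The comparison of both genotypes asks which genes depend on phytochrome B in red light. PHYB itself (AT2G18790, chromosome 2, positions 8139756 to 8144461 on the plus strand in the TAIR10.1 reference) had 36.3 RPKM in WT and 14.1 RPKM in phyB, a log2 ratio of -1.36 with a 95% counting interval from -1.45 to -1.28. The labels name no allele, and a transcript that remains detectable does not contradict a mutant label. Among the other photoreceptors of the family, PHYA was at 159 and 170 RPKM (log2 ratio 0.10), PHYD at 0.10 and PHYE at -0.20, while PHYC was lower in phyB at -0.45. These genes are long. With the trend on coding length described below removed, PHYA stood at 0.30, PHYD at 0.31, PHYE at 0.002 and PHYC at -0.25. Transcripts of 3 phytochrome-interacting factors, bHLH proteins that promote elongation growth, were lower in phyB: PIF5 by a log2 ratio of -1.34 (67.3 to 26.6 RPKM), PIF4 by -1.25 (61.1 to 25.7 RPKM) and PIF7 by -1.14 (8.86 to 4.02 RPKM). PIF3 was higher at 0.50 and PIF1 lower at -0.23.

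Across the 19297 genes with a mean of at least 1 RPKM, 618 were at least 2-fold higher and 421 at least 2-fold lower in phyB, which together made 5.38%. At least 4-fold differences were seen for 83 genes in the higher and 72 in the lower direction. The median log2 ratio was -0.01, with quartiles at -0.25 and 0.26. Without a replicate these are counts of genes by size of difference in these columns, not calls. For 244 of the higher and 195 of the lower genes the 95% counting interval lay wholly beyond 2-fold, an interval that covers counting error only.

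**Figure D1:**
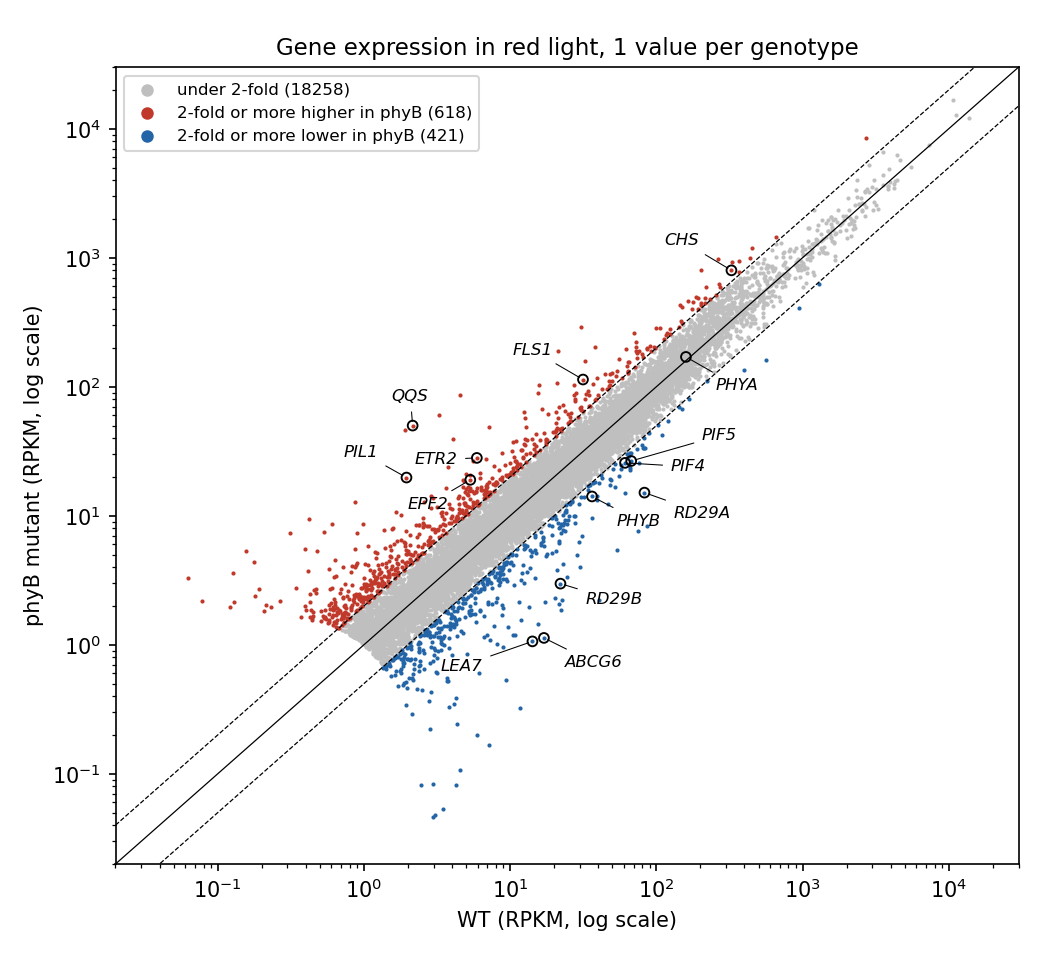
RPKM of each gene with a mean of at least 1 RPKM in WT (x axis) and the phyB mutant (y axis), both on log scales, with genes at least 2-fold higher in phyB in red and at least 2-fold lower in blue. The solid line marks equal values and the dashed lines 2-fold, genes without reads in a column are drawn at the value the authors wrote for 0 reads, and PHYB, PIF4 and PIF5 lie below the lower dashed line.

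The largest differences in the higher direction among nuclear genes with a mean of at least 5 RPKM were in AT5G62210, an embryo-specific protein 3 family gene (1.91 to 46.4 RPKM, log2 ratio 4.60), QQS, which acts on starch content (2.15 to 50.0 RPKM, 4.54), AT2G01008 (4.25), AT5G57760 (3.27 to 60.2 RPKM), the glycine-rich protein gene AT3G02670 (3.88) and PIL1, a bHLH gene induced by shade (1.96 to 19.8 RPKM, 3.34). The largest in the lower direction were in the GDSL-type lipase gene AT3G50400 (11.6 to 0.321 RPKM, -5.18), PELPK2, a hydroxyproline-rich cell wall protein gene (40.4 to 2.22 RPKM, -4.18), ABCG6, a transporter gene of suberin formation (17.0 to 1.13 RPKM, -3.91), LEA7, a late embryogenesis abundant protein gene (14.2 to 1.06 RPKM, -3.74), AT2G16005 (-3.58) and the cyclophilin-like gene AT3G55920 (-3.42). The 95% counting intervals of these 12 genes all excluded ratios of 4-fold or less. AT5G57760, AT3G02670, LEA7 and AT3G55920 overlap a gene on the opposite strand, and AT2G01008 one on the same strand, so their reads can come partly from the neighbour.

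Genes of flavonoid and anthocyanin biosynthesis were higher in phyB. Of 20 measured members 11 were at least 2-fold higher, none was 2-fold lower, and the list median of 1.2 exceeded that of all 10000 random lists matched on mean expression. FLS1, which makes flavonols, went from 31.5 to 114 RPKM (1.85), LDOX of the anthocyanin branch from 3.15 to 11.6 RPKM (1.89) and UGT79B1, an anthocyanin glycosyltransferase, from 2.37 to 8.52 RPKM (1.84). TT19, a transporter-type glutathione transferase, was higher at 2.24, but overlaps PSY on the opposite strand. CHS, the entry enzyme of the pathway, went from 326 to 799 RPKM (1.29).

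The shade-avoidance list, genes raised when the ratio of red to far-red light is low, had a median of 0.41, above that of all 10000 random lists, although only PIL1 (3.34) and the cytokinin oxidase gene CKX5 (1.53) of its 20 members were at least 2-fold higher. The early auxin-response list had a median of 0.48, above all random lists, and its members differed by family, a division made after the values were seen and not tested. IAA19 and IAA29 are in both lists, so these are not fully separate evidence. The shade-avoidance list also shares XTH15 with the expansin list, PRE1 with the brassinosteroid list and FHL with the light-signalling list. All 14 measured SAUR genes, small auxin-induced growth genes, had ratios above 0, with a median of 1.12 and 10 at 2-fold or more, while 12 of the 17 other members had ratios below 0, with a median of -0.27 and none at 2-fold or more in either direction. SAUR65 stood at 1.92 and SAUR22, SAUR23 and SAUR21 at 1.83, 1.80 and 1.63. However, 9 of the 14, these last 3 among them, have near-identical copies among which the authors' counting could have divided reads. They are not independent members, and the position of the list without them was not computed. The 5 SAUR genes without such a copy had a median of 1.02, with 3 at 2-fold or more. SAUR genes are short, and with the trend on coding length described below removed the median of all 14 was 0.82, with 6 at 2-fold or more, and that of the 5 without a copy 0.79, with 1 at 2-fold or more. Expansin and xyloglucan endotransglucosylase genes, which loosen cell walls, did not stand apart as a group (29 members, median 0.05, percentile 58.7). EXPA2 was higher at 1.31 and EXPA16 lower at -1.19.

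Ethylene genes had a median of 0.65, above that of all 10000 random lists. Of 16 members 4 were at least 2-fold higher and none was 2-fold lower, among them the receptor genes ETR2 (5.92 to 28.1 RPKM, 2.25) and ERS1 (1.07), EBF2, an F-box protein gene of the pathway (1.21), and the biosynthetic gene ACO1 (1.12). Stomatal lineage genes had a median of 0.82, above all random lists, with 4 of 9 members at least 2-fold higher. EPF2 was at 1.83 and EPF1 at 1.43, both peptides that limit stomatal formation, and TMM, their receptor-like partner, was at 1.19. MUTE, a transcription factor of the lineage, was at 1.42. Heat-shock genes, listed as a sign of sample state, had a median of 1.35, above all random lists, and 7 of 9 were at least 2-fold higher. HSP17.6II went from 1.78 to 10.1 RPKM, and HSFA2 was at 1.81, HSP17.4 at 1.62 and HSP90.1 at 1.35.

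Circadian clock genes were lower in phyB. Of 25 members 22 had ratios below 0 and 4 were at least 2-fold lower, namely RVE1 (36.6 to 9.55 RPKM, -1.94), PRR5 (-1.61), ELF4 (63.0 to 27.9 RPKM, -1.18) and CDF1 (-1.12), and the median of -0.45 lay below that of all 10000 random lists. The labels give no time of day for the harvest. The 5 measured flowering-time regulators all had ratios below 0 (median -0.76, percentile 0.01), with COL2 at -0.98 and SOC1 at -1.26. Cold-response genes had the lowest median of the 20 lists, -1.25, below all 10000 random lists, and all 8 measured members had ratios below 0. RD29B went from 22.1 to 2.98 RPKM (-2.89), RD29A from 82.9 to 15.1 RPKM (-2.46), and COR15B from 6.02 to 2.55 RPKM (-1.24), and CBF2 (-1.26) and CBF3 (-1.88) were the other members at 2-fold or more. Jasmonate and salicylate genes had a median of -0.42 (11 members, percentile 0.13), with JAZ9, the member of highest mean, at -0.42 and VSP1 and VSP2 the only 2-fold lower members at -1.33 and -1.76.

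The list of photoreceptors and light-signalling genes had a median of -0.24 (28 members, percentile 0.20), with PHYB, PIF4, PIF5 and PIF7 its only members at 2-fold or more. Its percentile was 3.06 against random lists matched also on coding length, but 0.06 with the length trend removed. None of 44 nuclear photosynthesis genes differed 2-fold. Their median of -0.01 was at percentile 1.08, against 0.17 for the median of the random lists, and quantile normalization moved the percentile to 21.5. LHCB1.3, which has near-identical copies, was at -0.18. None of 18 chlorophyll biosynthesis genes differed 2-fold (median 0.25, percentile 94.7, but 99.8 with the length trend removed and 99.99 against lists matched on length). The list was mixed, with 11 ratios above 0, 7 below 0 and a mean of 0.08, and CRD1 was at -0.13. None of 12 carotenoid genes did so either (median -0.14, percentile 11.2), and PSY was at -0.28. Gibberellin genes had a median of -0.04 (percentile 40.3), with GA2OX1, which inactivates gibberellins, at -1.05. Brassinosteroid genes had a median of -0.16 (percentile 5.54) and a mean of 0.02, which differ in sign, with BEE3 higher at 1.99 and PRE5 at 1.31.

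Among lists of other tissues and states, root and root-hair markers had a median of -0.25 (15 members, percentile 1.42, and 4.08 on the log2(RPKM + 1) scale), with none at 2-fold and BGLU23 at -0.46. Dividing-cell and shoot-apex markers had a median of 0.02 (percentile 64.5), with AS1 at 0.31. Seed storage and oil-body markers had a median of -0.28 (11 members, percentile 4.37, and 0.32 with the length trend removed), with the late embryogenesis gene EM6 at -3.18, EM1 at -1.46 and SESA1 at 1.01. CHS, SOC1, CBF2, CBF3, VSP1, VSP2, MUTE, EM1 and SESA1 were chosen after their values were seen. The percentiles describe these columns and are not tests across replicates.

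**Figure D2:**
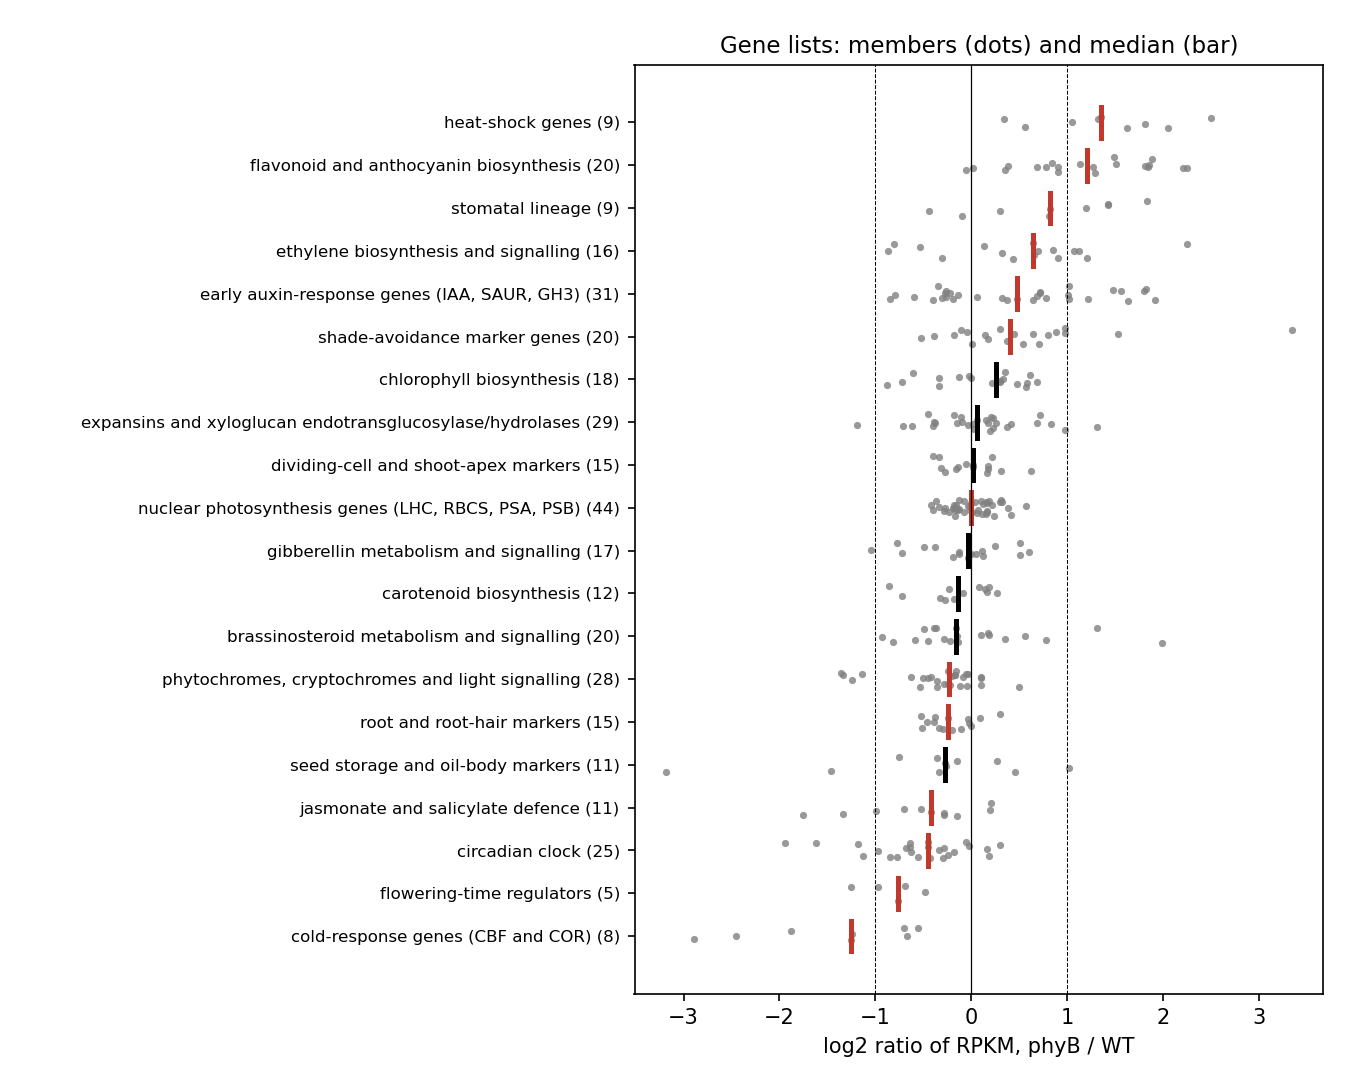
Log2 ratio of RPKM in phyB over WT (x axis) for the measured members of each gene list (dots, their number in parentheses) and the list median (bar, red where it lay outside the 2.5 to 97.5 percentiles of random lists), with dashed lines at 2-fold. Heat-shock and flavonoid genes had the highest medians, 1.35 and 1.2, and cold-response genes the lowest, -1.25.

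The ratio followed coding length. The median log2 ratio was 0.39 over the 919 genes shorter than 300 nt and -0.21 over the 1375 genes of 2700 nt or more. With this trend removed, 450 genes were at least 2-fold higher and 498 at least 2-fold lower, so the excess of higher genes did not hold. Genes encoded in the mitochondria had a median of 1.19 (66 genes, 38 at least 2-fold higher) and those of the chloroplast 0.46 (88 genes, 11 at least 2-fold higher). The 34 gene models of chromosome 2 with codes from AT2G076 to AT2G078, a region that holds a copy of mitochondrial DNA, had a median of 1.23 with 20 at least 2-fold higher. These 20 are counted among the 569 nuclear genes that were 2-fold higher, and reads of all 34 models can come from mitochondrial transcripts.

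**Figure D3:**
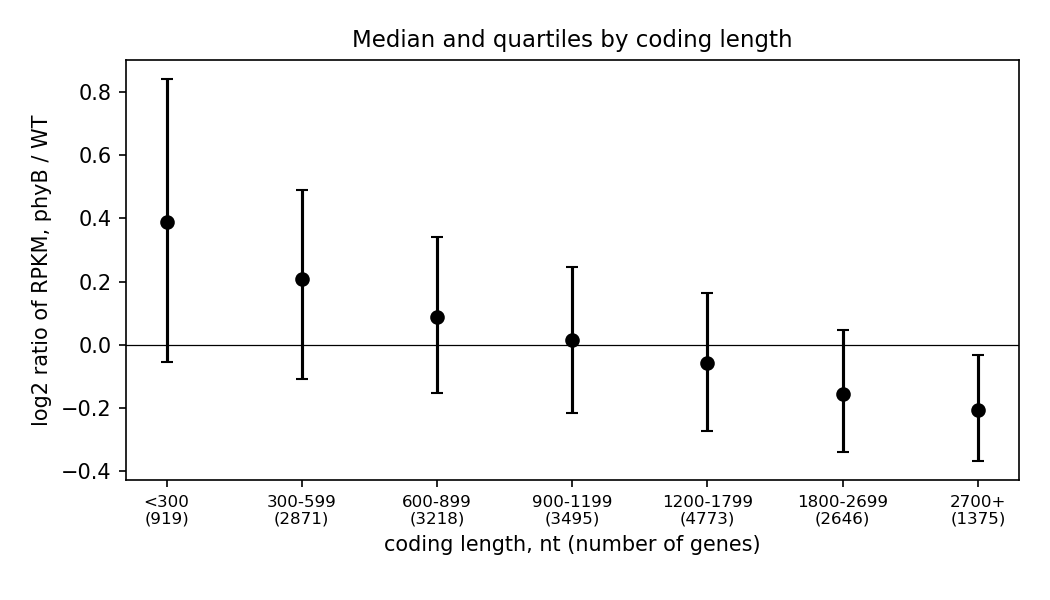
Median (points) and quartiles (bars) of the log2 ratio of RPKM in phyB over WT (y axis) for genes grouped by coding length in nt (x axis, number of genes in parentheses). The median went from 0.39 in the shortest class to -0.21 in the longest.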

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

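Chosen after the data were seen were the TMM factors, the removal of the coding-length trend, the totals without organelle genes, the counting interval beyond 2-fold and the random lists matched on coding length. Against 1039 genes at 2-fold or more (618 higher and 421 lower in phyB), the count was 622 (375 and 247) on the log2(RPKM + 1) scale, 2302 (1399 and 903) with no filter on low values, 518 (321 and 197) at a mean of at least 5 RPKM, 371 (211 and 160) at an absolute log2 ratio of 1.5, and 439 (244 and 195) where the 95% counting interval lay wholly beyond 2-fold. These follow from the construction of each criterion. The other settings gave 948 to 1068 genes. Removal of the coding-length trend turned the split from 618 and 421 to 450 and 498. It moved PHYB from -1.36 to -1.16, and the other 8 settings left PHYB between -1.37 and -1.30. Of 130 genes whose ratio was recomputed under 9 settings, none at 2-fold or more changed sign. Median scaling, the RLE, TMM and upper-quartile factors and the totals without organelle genes shift every ratio by 1 small constant. The largest was 0.046, for upper-quartile factors. A pseudocount cannot turn a sign, so this outcome was largely fixed by construction. Of the 86 at 2-fold or more, 76 stayed there on the log2(RPKM + 1) scale, 84 with the length trend removed and 86 under each other setting. The ratio left its counting interval for 36 genes with the length trend removed, 22 on the log2(RPKM + 1) scale, 19 with quantile normalization, 14 with upper-quartile factors and 3 with median scaling. The 6 lists above and 7 below the random lists became 6 and 6 with quantile normalization and on the log2(RPKM + 1) scale, 7 and 8 with the length trend removed, and 7 and 6 with lists matched on coding length. The photosynthesis list no longer stood apart with quantile normalization, the root list on the log2(RPKM + 1) scale and the light-signalling list with matching on length. The median of the chlorophyll list stood apart as higher with either length setting (percentiles 99.8 and 99.99), although 7 of its 18 members had ratios below 0 as deposited. The seed list stood apart as lower with the trend removed (median -0.44). No paired analysis was possible because each genotype has 1 value column that carries no replicate number. For the same reason leaving out a replicate, the DESeq2 and limma tests, and the set tests with an estimated correlation or fry were not run.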

Other observations

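The gene lists in the next paragraph, apart from the root and root-hair markers, were chosen only after the values were seen. The same holds for the genes named there and for the tests of organelle carry-over, of seed remains, and of harvest, water status or batch.

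Genes of abscisic acid and dehydration responses were lower in phyB, with a median log2 ratio of -0.97 over 22 measured members and 11 at least 2-fold lower. RD29A and RD29B are also in the cold-response list and EM6 in the seed list, so these lists are not separate evidence. The phosphatase gene HAI1 was at -2.47, LEA4-5 at -2.23 and the dehydrin gene RAB18 at -2.15, whereas the receptor gene PYL6 was higher at 2.22. Suberin biosynthesis genes had a median of -1.10 over 13 members with 7 at least 2-fold lower, among them GPAT7 (-3.35), CYP86B1 (-3.20) and GPAT5 (-2.93), and FAR1 (AT5G22500) was higher at 0.84. The 6 genes examined of the marneral and thalianol clusters, triterpene pathways of the root, were each at least 2-fold lower, with a median of -1.61 and MRN1 at -3.38. Of 15 root and root-hair markers 13 had ratios below 0 but none was 2-fold lower, with a median of -0.25 at percentile 1.42, or 4.08 on the log2(RPKM + 1) scale. The cytokinin list had a median of -0.28 over 13 members (percentile 1.24), with CGA1, a GATA factor of chloroplast development, at -2.52 and ARR16 at 1.08. The lipid-transfer-type gene EARLI1 was higher at 3.25 and its neighbour AZI1 at 1.90, and PELPK1 was lower at -3.29. Apart from the root and root-hair markers, these lists were picked for their values, so their percentiles carry no independent weight.

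Genes with short coding sequences were higher in phyB, by a difference of medians of 0.40 between nuclear genes under 600 nt and those of 1800 nt or more. Bootstrap intervals here and below came from 2000 draws of genes within these columns. They treat genes as independent and hold no variation between libraries or seedlings. Ribosomal protein genes do not carry the trend, since the difference was 0.38 (bootstrap interval 0.36 to 0.40) without them. They were themselves higher in phyB, with a median of 0.59 over 317 genes, or 0.42 with the trend removed. Of these 302 had ratios above 0 and 22 were at least 2-fold higher. GC content does not either, since the mean difference within 10 classes of GC content was 0.39 (0.37 to 0.41). A length-dependent difference between the libraries, such as in RNA integrity or fragment size, may lie behind it and stays open: the difference was positive in all 5 classes of mean expression, but the smallest, 0.22 in the lowest class, had an interval from 0.15 to 0.30 that reaches below the 0.2 set in advance. No biological explanation was tested.

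Mitochondrial transcripts were higher in phyB with a median of 1.19. The coding-length trend does not account for this, since the median was 0.95 (0.80 to 1.19) after its removal. The mitochondrial median exceeded that of the chloroplast by 0.73 (0.38 to 0.98), so genes of both organelles were not higher to the same extent in these columns. The limits for this comparison were set after the values were seen. It therefore excludes no explanation, and carry-over that differs between the organelles stays open. Nuclear genes of the respiratory complexes did not follow to the same extent. Their median over 76 genes was 0.40 as deposited, with 71 above 0 and 8 at least 2-fold higher, and 0.17 (0.11 to 0.25) after removal of the trend. These genes were picked by product name, and the chromosome 2 models described above were not left out. Any of those models in the set can carry reads of mitochondrial transcripts. Because the RNA was selected for poly(A) tails, a difference in that selection or in mitochondrial RNA itself may be involved, which was not tested.

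Cold-response and dehydration genes were lower in phyB. The coding-length trend does not account for this, since the cold-response median was -1.42 (-2.31 to -0.98) after its removal. Seed remains in the WT sample stay open, because the outcome depends on the genes counted: the 9 seed storage protein and oleosin genes, a set defined after the values were seen, had a median of -0.26 (-0.36 to 0.45), or -0.32 (-0.53 to 0.49) with the length trend removed, within the bound set for exclusion. The whole seed list of 11, which adds the late embryogenesis genes EM1 (-1.46) and EM6 (-3.18), had a median of -0.28 (-0.75 to 0.27), or -0.44 (-0.93 to 0.34) with the trend removed, and both intervals pass that bound. EM6 is also a member of the dehydration list, so its low value is part of the pattern to be explained and no separate sign of seed remains. A difference of harvest, water status or sequencing batch may explain the pattern and cannot be told apart from the genotype, whose effect stays untested, with 1 value column per genotype, and heat-shock genes, listed as a sign of sample state, differed between the same columns, with 9 of 9 above 0 and a median of 1.35.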
